A study of Caenorhabditis elegans with 12 samples.

How the data were processed

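Polyadenylated RNA from whole, mixed-stage worms grown at 20 °C was made into directional libraries and sequenced as paired 75 nt reads with 9 libraries per lane, per the labels' protocols. The 12 libraries therefore needed more than 1 lane, and the lane of each library is not given in the sources used here. Per the submitters' processing notes, cutadapt, Bowtie2, STAR and SAMtools were used on the ce10 build, with no versions stated and no role or order given. The deposited values are scores attached to the included and excluded form of each alternative splicing event, in a pair of tracks per library. Per the file headers, the first track holds alternative 3' and 5' splice site events found from introns seen in the libraries, and the second holds alternative first exons, alternative last exons, mutually exclusive exons, skipped exons, runs of several skipped exons and retained introns from Ensembl archive 65. The headers call the events merged, and each library has its own tracks.

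In the track of library introns, the scores of the included and excluded form summed to 1000 in every event, so the deposited score is percent spliced in (PSI) as a fraction times 1000, with a PSI of 0 or 1 written as 1 or 999. In the annotated track both scores of an event carry a further factor of at most 1 whose meaning is not given in the sources used here. PSI there was computed as the included score over the sum of both scores, which removes the factor. The read minimum and the formula behind PSI are not given in the sources used here. Neither track holds read counts, so the depth of a library is unknown and the reads behind a PSI could not be counted. Values such as 33.33%, 50% and 66.67%, which few reads would give, recur among the named events. More reads can give such values too. Between 36.8% and 49.2% of donor and acceptor events stood at 0 or 1 in a library, a share that can grow as depth falls but also reflects real use of 1 site. The design written before the data were examined allowed for read counts with a count-based test and named limma for the case that only PSI was given, and the latter applied. It also took the event sets to overlap, whereas they hold different event types, so donor and acceptor counts come from the library introns alone and all other types from the annotation.

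Libraries were grouped by the strain in the labels, as control, PRP-8 R540K, PRP-8 D1549N and SNRP-200 N18K with 3 libraries each, and replicates were numbered in accession order, which pairs nothing across strains. Events with a PSI in all 12 libraries were tested, 10291 of 12353 from library introns and 2207 of 2586 annotated ones, of which 294 had the same PSI in every library. PSI as a fraction was fitted with limma 3.58.1 in R 4.3.3, with all 4 strains in 1 fit (8 residual degrees of freedom, prior degrees of freedom 0.579 and 0.445) and Benjamini-Hochberg adjustment within each event set and comparison. An event was called at an adjusted p below 0.05 and an absolute difference of mean PSI of at least 10 points. Standard errors are those of limma's moderated test. Tests of event types are two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 24 tests, and tests of direction are two-sided exact binomial tests with 1 event per gene, the one with the largest difference, or per group of overlapping events where no gene was matched, and 95% Wilson intervals. SciPy 1.17.1 and pandas 2.3.3 under Python 3.11 were used for these. Both kinds of test count events or genes as independent, although all come from the same libraries, so their p-values and intervals leave out the spread between libraries. Overlaps between strains were set beside the number for independent lists, and overlaps and covariances of PSI differences beside those in 100 simulations of unchanged strains with shared control libraries.

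Applied to simulated data with changes placed in D1549N, the fit to 10291 library-intron events recovered 39% of 100 changes of 15 points and 65% of 100 changes of 30 points, and 3.7% of its calls were false. For the 2207 annotated events it recovered 64% and 85%, and 1.97% of its calls were false. The simulated noise was normal and independent for each event and library, with no difference shared by the events of a library and no sampling of reads. These shares therefore need not hold for the real calls. The simulations of unchanged strains used the same kind of noise.

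No genome of the ce10 build was used here, so the bases around splice sites were not examined. The tracks name no genes. Gene names come from the WBcel235 annotation of Ensembl release 115, by matching intron lengths and the spacing of neighbouring introns without converting any coordinate: an event took a gene where at least 4 neighbouring introns within 80000 bp matched in length and spacing, with at least 2 times the support of the next placement. This named 9407 of 12353 library-intron events (76.2%) and 2217 of 2586 annotated events (85.7%), and 22 and 11 more matched several genes and were left unnamed. A site is called annotated where its intron matched one in that annotation, and coding or UTR as that annotation has it. Events in near-identical gene copies may draw reads from each other, since the treatment of reads that map to several places is not given in the sources used here.

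The genes named follow a rule fixed before the data were examined. For each mutant against the control, called events whose 3 mutant values did not overlap the 3 control values, which chance gives for 10% of events, were ranked by their difference in mean PSI with 1 event per gene. The 12 largest donor events and the 12 largest of all other types, with at most 4 retained introns, were taken, and the 6 largest for each comparison between mutants. To these came unc-73, prp-8 and snrp-200 where they had an event, and up to 4 called members of each of 10 gene lists fixed at the same time: U5 and U4/U6 proteins, other spliceosomal proteins, SR proteins and splicing regulators, ribosomal proteins with isoforms known to undergo nonsense-mediated decay, muscle, neuronal, cuticle, germline and intestinal genes, and the genes that mark the strains. Further members of the splicing regulator list and the events called in all 3 mutant strains were named after their values were seen. Alternatives were a stricter and no minimum difference, limma on logit PSI with PSI kept within 0.01 to 0.99, a fit to the 6 libraries compared, a rule that all 9 library pairs differ by at least 15 points in 1 direction, 1 event per gene and each library left out in turn. For annotated events only the stricter minimum, logit PSI and leaving out libraries were planned, and no minimum, the 6-library fit, the rule on library pairs, 1 event per gene and retained introns left out were added after the data were seen. Overlaps with 1 strain called against 1 control library alone, whose spread is then taken from the other libraries, events at 0 or 1 left out, limma with trend and robust settings, and leaving out an N18K library in the other comparisons were added after the data were seen.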

Results

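Splicing was measured in polyadenylated RNA from whole, mixed-stage Caenorhabditis elegans of 4 strains, with 3 libraries per strain and 12 libraries in all. Every strain carried unc-73(e936), an allele with a mutated 5' splice site beside which cryptic donors are used. The mutant strains carried suppressors of that cryptic splicing. R540K and D1549N are changes in PRP-8, the large U5 snRNP protein at the core of the spliceosome, and N18K is a change in SNRP-200, the Brr2 helicase that unwinds U4/U6 RNA. The question was which native splicing events differed between each mutant strain and the control strain. Each event had a pair of competing forms, and its value was percent spliced in (PSI), the share of the form marked as included. At alternative 5' splice sites PSI was the use of the downstream donor, at alternative 3' splice sites the use of the upstream acceptor, and at retained introns the share left unspliced. Donor and acceptor pairs up to 50 nt apart numbered 11691 to 11963 per library, and annotated events of the other types 2389 to 2478. A PSI in all 12 libraries was required, which left 4539 donor pairs, 5752 acceptor pairs and 2207 annotated events. Read counts were not given in the sources used here, so the depth behind each PSI is unknown and no counting interval is given. A PSI printed as 0.1% or 99.9% is the lowest or highest value the files hold. Nothing in the labels says that libraries of a strain came from separate cultures, so limma p-values measure the spread between these libraries, which may be technical. Binomial and Fisher's exact tests, those of retained introns among them, count genes or events as independent although all share the same libraries. Their p-values do not measure that spread. A call needed an adjusted p below 0.05 in limma and a difference of at least 10 PSI points, and all positions are on the ce10 build.

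In worms with PRP-8 D1549N, donor choice shifted in 297 genes or unnamed loci, and a smaller group of introns was retained more often. At Y41C4A.12, use of the downstream donor of a coding pair 4 nt apart was 95.98% ± 0.33 (SD, n = 3) in the mutant and 12.2% ± 3.71 (n = 3) in the control. The cytochrome P450 gene cyp-31A5 went the same way at another 4 nt pair, from 1.12% ± 0.97 to 84.8% ± 13.6 (n = 3 each). At del-5, a gene of the DEG/ENaC channel family, use of the unannotated downstream donor fell from 80.9% ± 8.96 to 8.14% ± 5.03 (n = 3 each). Retention of an intron of cdc-26, which encodes a subunit of the anaphase-promoting complex, rose from 19.3% ± 0.96 to 85.2% ± 2.12 (n = 3 each). The Y41C4A.12 pair lies at chromosome III, 11724023 to 11724208, and its PSI rose by 83.8 points (SE 4.47; limma, adjusted p = 8.07e-06). The coding cyp-31A5 pair, at chromosome IV, 13402809 to 13403694, rose by 83.7 points (SE 5.47; limma, adjusted p = 2.6e-05). The coding del-5 pair, at chromosome X, 11006452 to 11006663, fell by 72.8 points (SE 6.84; limma, adjusted p = 0.000247). The cdc-26 intron lies in the coding region at chromosome I, 10639346 to 10639740, and rose by 66.0 points (SE 1.65; limma, adjusted p = 1.39e-07). F19C6.8, a noncoding transcript at chromosome X, 9997699 to 9997894, used its unannotated downstream donor at 75.4% ± 21.3 against 0.1% in every control library (n = 3 each).

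Counted over all tested donor and acceptor pairs, 451 of 10291 were called in D1549N, 178 with a higher and 273 with a lower PSI. Of the 12 largest donor changes, 8 had no matched gene, among them pairs at chromosome IV, 3137105 to 3137693 (PSI up by 82.6 points) and chromosome III, 6121421 to 6121867 (up by 76.6 points). The latter stood at 0.1%, 20% and 0.1% in the control and at 75%, 99.9% and 75% in D1549N, values that few reads can give. Alternative donors made up most of the calls. D1549N changed 321 donor pairs, or 7.07% of those tested, against 130 acceptor pairs, or 2.26%. Against all other event types together, donor pairs had an odds ratio of 2.85 (Fisher's exact test, adjusted p = 7.43e-30 over 24 tests), and 4.37 without control replicate 3 and 4.65 and 4.34 without D1549N replicates 1 and 3. The fit shares its estimate of spread over all strains, and without N18K replicate 3 D1549N had 511 calls at donor and acceptor pairs. The odds ratio was not computed for that fit. With 1 event per gene or locus the odds ratio of donor against acceptor pairs was 3.07 (Fisher's exact test, p = 1.48e-25). Genes and unnamed loci split about evenly between less and more use of the downstream donor, 157 against 140 of 297 (52.9% less, 95% Wilson interval 47.2% to 58.5%; exact binomial test, p = 0.353).

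**Figure D1:**
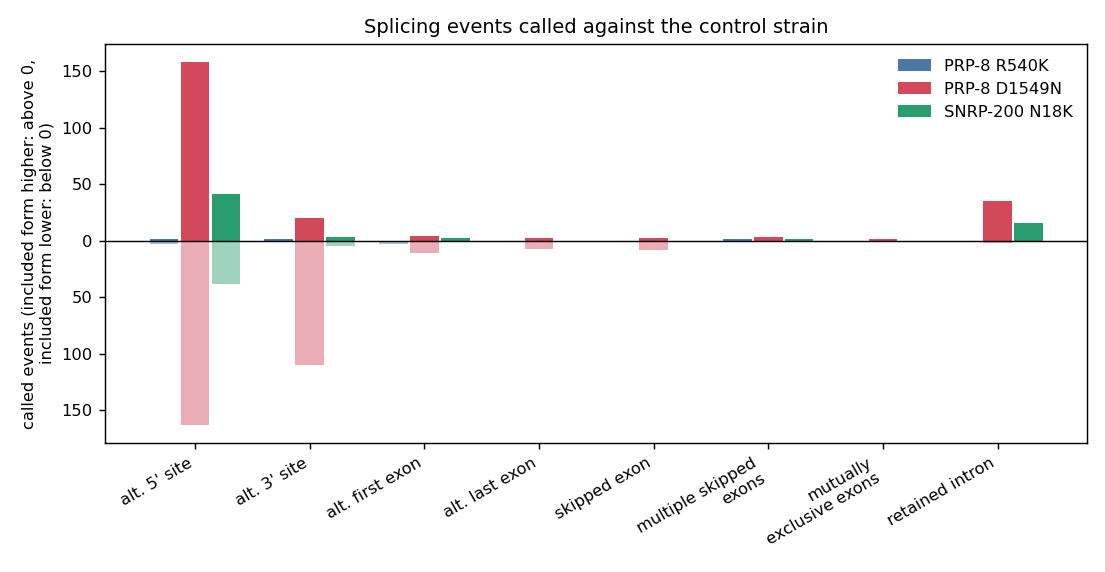
Called events of each type in each mutant strain against the control strain, with events whose included form was higher drawn above 0 and events whose included form was lower drawn below it. Donor pairs lead in D1549N (158 higher, 163 lower) and N18K (41 higher, 38 lower), acceptor changes in D1549N lie mostly below 0 (110 of 130) and retained introns above it (35 of 37).

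The direction differed with the distance between the donors, a grouping chosen after the data were seen. Where the donors lay 4 nt apart, D1549N raised the downstream donor in 38 genes or unnamed loci, Y41C4A.12 and cyp-31A5 among them, and lowered it in 8, del-5 among them (exact binomial test, adjusted p = 6.47e-05 over 28 tests). Where they lay 3 nt apart, all 29 called genes or unnamed loci moved away from the downstream donor (exact binomial test, adjusted p = 7.29e-08), including unc-40, the netrin receptor, which fell by 15.2 points (SE 1.08; limma, adjusted p = 4.62e-05). Only the upstream donor was annotated in 27 of the 38 risen 4 nt pairs, and only the downstream donor in 16 of the 29 fallen 3 nt pairs. Over the 38 pairs the mean PSI was 42.8% ± 0.32 in D1549N and 14.4% ± 0.56 in the control, beside 14.9% ± 0.87 in R540K and 16.8% ± 0.66 in N18K (SD, n = 3 each). The 29 pairs had means of 52.8% ± 1.53 in D1549N, 83.0% ± 1.19 in the control, 81.6% ± 0.64 in R540K and 79.0% ± 0.98 in N18K (n = 3 each). These pairs were chosen for their difference in D1549N, so the choice adds to the gap. The binomial tests take both directions as equally open, whereas control means of 14.4% and 83.0% left more room in the direction taken. Distance and starting use were therefore not separated. Over all 669 tested pairs 4 nt apart, called or not, library means ran from 32.49% to 32.86% in D1549N and from 30.17% to 31% in the other 9 libraries, and over all 263 pairs 3 nt apart from 69.62% to 70.64% and from 73.86% to 75.26%. Among called donor pairs of D1549N with 1 annotated donor, 153 of 176 genes moved toward the unannotated donor. Of those whose control use of the unannotated donor lay between 20% and 80%, 11 of 24 did (exact binomial test, p = 0.839).

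**Figure D2:**
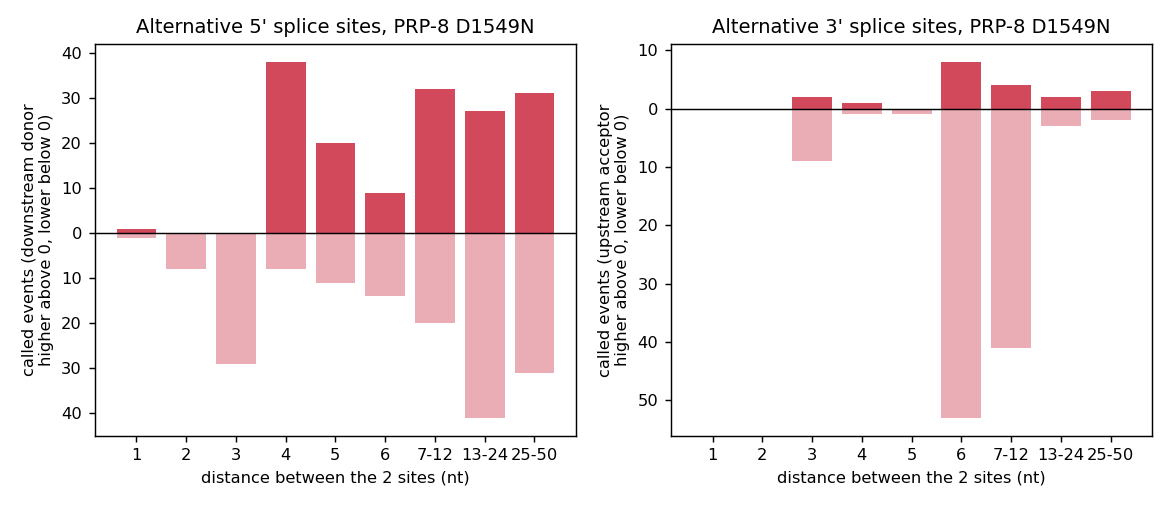
Called donor pairs and acceptor pairs in D1549N by the distance between the competing sites in nt, with higher PSI above 0 and lower PSI below it. Donor pairs 3 nt apart lie wholly below 0 (29 events), donor pairs 4 nt apart mostly above it (38 of 46), and acceptor pairs 6 nt apart mostly below it (53 of 61).

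Acceptor choice in D1549N moved mostly away from the upstream acceptor, in 106 of 126 genes or unnamed loci (84.1%, 95% Wilson interval 76.8% to 89.5%; exact binomial test, p = 2.45e-15). The test and interval count genes as independent trials, but all came from the same libraries. Acceptor use also differed between libraries of 1 strain, as given below. Neither value therefore measures support for an effect of the strain. At icd-2, the alpha subunit of the nascent polypeptide-associated complex, use of the upstream acceptor of a coding pair 6 nt apart fell from 61.7% ± 2.53 to 25.8% ± 4.37 (n = 3 each; chromosome I, 536242 to 536427; limma, adjusted p = 0.011). B0001.7 fell from 46.0% ± 3.91 to 7.5% ± 1.2 at a pair 12 nt apart, F28H6.6 fell by 40.6 points and C56A3.6 fell by 32.2 points, whereas F58H1.7 rose by 35.3 points. The crh-1 gene, which encodes the worm CREB, had a called acceptor pair that fell by 38.5 points, a call lost without control replicate 2 or D1549N replicate 1. Over all 893 tested pairs 6 nt apart, called or not, the mean use of the upstream acceptor was 43.01% ± 0.34 in the control, 42.7% ± 1.98 in R540K, 38.3% ± 1.0 in D1549N and 39.6% ± 3.48 in N18K (SD, n = 3 each). The range within the N18K libraries, 6.54 points, was larger than the drop of 4.69 points in D1549N, and it rests on N18K replicate 3. Ranges were 0.66 points in the control, 3.84 in R540K and 1.99 in D1549N.

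Among annotated events, D1549N changed 77 of 2207, with 47 higher and 30 lower. Retained introns gave 37 of these calls, and 35 of the 37 rose. The 2 that fell lay in cdc-26 and ltah-1.1, genes with a larger rise at another intron, so by the largest change of each gene 35 of 35 rose (exact binomial test, p = 5.82e-11). As a type, retained introns were called in 5.12% of those tested against 4.17% of other types (odds ratio 1.24; Fisher's exact test, adjusted p = 0.43). Introns of F46H5.2, T22D1.3 and T19D12.2 followed cdc-26 with rises of 52.5, 49.4 and 42.98 points. Among the lists fixed beforehand, SR proteins and splicing regulators had calls in 7 of 22 tested genes, with 9 events over all events and 10 adjusted over the list alone. Of the 9 called events, 5 rose and 4 fell. The share of called genes was 31.8% against 7.54% of other genes (Fisher's exact test, adjusted p = 0.0269 over lists and strains), but these genes averaged 4.27 tested events against 2.05 in other genes. With the number of tested events matched, chance gave 3.47 called genes against the 7 seen (permutation test, one-sided, p = 0.0341, unadjusted and chosen after the data were seen). Retained introns rose in the SR protein genes rsp-5 (17.3% ± 2.49 to 57.04% ± 0.93, n = 3 each, in the 3' UTR at chromosome II, 6490769 to 6491030; limma, adjusted p = 0.000311) and rsp-6 (33.2% ± 3.88 to 71.8% ± 2.29, n = 3 each; limma, adjusted p = 0.000462), in swp-1, a homolog of suppressor of white apricot, and in rbm-5, an RNA-binding splicing regulator. The same strain lowered PSI at donor pairs of ptb-1, the polypyrimidine tract-binding protein, and hrpa-1, an hnRNP A1 homolog, and at acceptor pairs of rbm-5 and rbm-25.

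Of 7 tested genes on the list of ribosomal proteins with isoforms known to undergo nonsense-mediated decay, rpl-12 alone was called, with retention up from 30.6% ± 1.34 to 63.6% ± 0.23 (n = 3 each; chromosome IV, 13239802 to 13240374; limma, adjusted p = 0.000112; 1 event adjusted over the list alone). Neuronal genes had calls in 4 of 35 (3 events adjusted over the list alone), where unc-73 rose by 22.6 points at a pair 45 nt apart and unc-40, the synaptic RIM homolog unc-10 and the JIP3 homolog unc-16 fell. Muscle genes had a call in 1 of 29, a skipped exon of the troponin T gene tnt-3 up by 16.8 points (1 adjusted over the list alone), and cuticle genes in 1 of 9, a donor pair of the proprotein convertase gene bli-4 that fell by 16.4 points (1 adjusted over the list alone). The 4 lists of U5 and U4/U6 proteins, other spliceosomal proteins, germline genes and intestinal genes had no limma call over 56 tested genes, with 9 of 134 events at an unadjusted p below 0.05 and 0 called adjusted over the list alone. Calls of the rbm-5 intron, unc-10 and a first exon of the potassium channel gene unc-103 (50% against 99.9% in every control library) were lost on leaving out any 1 of the 6 libraries, those of unc-16 without control or D1549N replicate 3, and that of tnt-3 without control replicate 1 or 2 or any D1549N library. The unc-10 and unc-103 calls were also lost on logit PSI. The 77 annotated calls dropped to 51, 43 and 45 without control replicates 1, 2 and 3 and to 48 and 49 without D1549N replicates 1 and 2.

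In worms with SNRP-200 N18K, fewer events changed, and with all 3 libraries of the strain most were donor pairs together with a set of retained introns that all rose. The donor majority and the uniform rise depended on N18K replicate 3. Without it, acceptor calls outnumbered donor calls, 96 against 79, and 3 of 27 called retained introns fell while 24 rose. Donor calls numbered 79 in both fits, and 74 donor and acceptor pairs were called in both. At smi-1, use of the downstream donor of a coding pair 24 nt apart was 31.1% ± 8.45 in the mutant and 99.9% in every control library (n = 3 each). ZC262.2 used the downstream donor of a 5' UTR pair 7 nt apart at 47.6% ± 4.12 against 99.9% in every control library (n = 3 each). The gene hoe-1, which encodes the RNase Z that trims tRNA 3' ends, went the other way, from 27.3% ± 5.01 to 79.0% ± 0.64 for the unannotated downstream donor of a coding pair 10 nt apart (n = 3 each). Retention of an intron of Y50D7A.3 rose from 12.1% ± 1.22 to 48.1% ± 1.98, and one of the galectin gene lec-3 from 15.1% ± 3.28 to 49.96% ± 6.29 (n = 3 each). The smi-1 pair, at chromosome III, 1879476 to 1880242, fell by 68.8 points (SE 6.79; limma, adjusted p = 0.00182). The ZC262.2 pair, at chromosome III, 8332039 to 8332204, fell by 52.3 points (SE 1.63; limma, adjusted p = 2.61e-06). Its N18K values were 50%, 42.86% and 50%, which few reads can give, and every library of the other strains stood at 99.9%. The small SE therefore rests on strains without spread and does not measure the sampling of reads. The hoe-1 pair, at chromosome IV, 4743364 to 4744265, rose by 51.7 points (SE 3.35; limma, adjusted p = 0.000308). An overlapping alternative first exon event of hoe-1 rose by 42.0 points (limma, adjusted p = 4.21e-05). In the 3' UTR of pipp-4P, at chromosome III, 2824593 to 2825750, the downstream donor rose by 46.9 points (SE 1.96; limma, adjusted p = 9.65e-06). The receptor gene dmsr-1 fell by 59.8 points and M02B7.2 fell by 44.8 points, and the noncoding transcript WBGene00022335 rose by 63.5 points. The calls of dmsr-1 and WBGene00022335 were lost on logit PSI. Several of these changes were not particular to N18K. The D1549N libraries stood at 28.12%, 37.5% and 55.1% at smi-1 and at 16.28%, 13.89% and 30.77% at dmsr-1. At pipp-4P they stood at 85.71%, 81.56% and 87.61%, and at Y50D7A.3 at 49.58%, 40.59% and 42.08%. The lec-3 intron and M02B7.2 lay between the control and N18K in D1549N, while ZC262.2 and the hoe-1 donor pair stayed near the control.

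Of 10291 donor and acceptor pairs, N18K changed 87, with 44 higher and 43 lower. Donor pairs gave 79 calls and acceptor pairs 8, and donor pairs had an odds ratio of 4.84 against all other event types (Fisher's exact test, adjusted p = 5.99e-14). By gene or unnamed locus, 38 moved away from the downstream donor and 37 toward it, of 75 (exact binomial test, p = 1). Acceptor calls included B0001.7, which fell by 23.6 points and lost its call without control replicate 1, and F32D8.7, which rose by 19.9 points. Mean use of the upstream acceptor over the 893 pairs 6 nt apart was 38.2% and 37.0% in N18K replicates 1 and 2 and 43.5% in replicate 3. Without replicate 3 the calls were 175, of which 79 were donor pairs and 96 acceptor pairs, 93 of the latter lower, and the donor odds ratio was 0.832 (Fisher's exact test, p = 0.202). Without control replicate 1 there were 57 calls, and in a fit to the 6 libraries of these strains alone 17.

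Annotated events called in N18K numbered 21, with 19 higher and 2 lower, and all 16 called retained introns rose (exact binomial test, p = 3.05e-05). Retained introns were called in 2.22% of those tested against 0.781% of other types (Fisher's exact test, adjusted p = 0.00217). Splicing regulators had calls in 2 of 22 genes, both retained introns, with 4 events adjusted over the list alone (Fisher's exact test for the list, adjusted p = 0.499). The rsp-5 intron rose by 26.97 points (SE 3.5; limma, adjusted p = 0.00524), and a second rbm-5 intron, at chromosome I, 6216361 to 6216795, rose by 19.3 points, a call lost without any control library or N18K replicate 1 or 2. T19D12.2 retention was up by 32.03 points. On the muscle list, 1 of 29 genes was called, with 0 events adjusted over the list alone: the tropomyosin gene lev-11, whose mutually exclusive exons fell from 31.6% ± 3.7 to 18.4% ± 3.68 (n = 3 each; limma, adjusted p = 0.0386), a call lost without any control library or N18K replicate 2 or 3. First exon use rose by 19.7 points in mmaa-1, a homolog of the human methylmalonic aciduria gene MMAA, from a mean of 70.55% to 90.24%. It stood at 90.32%, 90.99% and 89.56% in the D1549N libraries. The other 8 lists had no limma call over 108 genes, with 28 of 296 events at an unadjusted p below 0.05 and 2 called adjusted over the list alone. Leaving out N18K replicate 3 gave 70 annotated calls. They were 27 retained introns (24 higher, 3 lower), 17 last exons (9 higher, 8 lower), 11 skipped exons (5 higher, 6 lower), 9 first exons (2 higher, 7 lower), 4 runs of skipped exons (2 each way) and 2 mutually exclusive exon events (both higher), where the full set had 0 calls of last exons and of skipped exons.

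**Figure D3:**
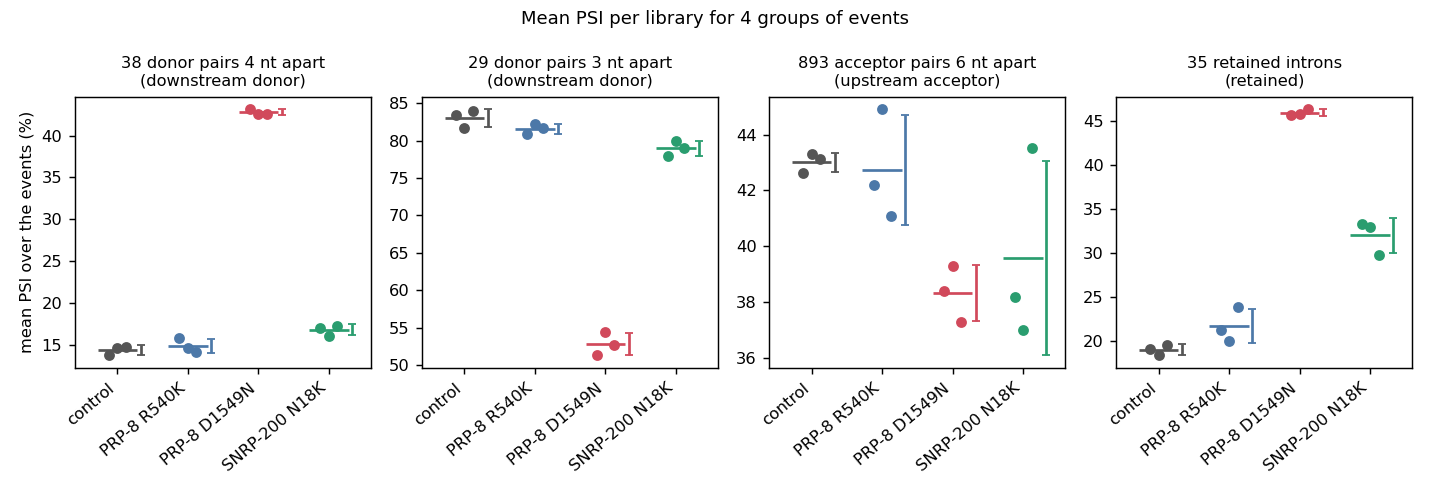
Mean PSI in percent for each library over 4 groups of events, with points for libraries, horizontal lines for strain means and bars for the SD of 3 libraries. D1549N stands apart for the 38 donor pairs 4 nt apart and the 29 donor pairs 3 nt apart, N18K lies between D1549N and the control for the 35 retained introns, and libraries of R540K and N18K spread widely for the 893 acceptor pairs.

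In worms with PRP-8 R540K, few events differed from the control. They included events of crh-1, the CREB transcription factor gene, and unc-52, the perlecan of the basement membrane under muscle. At crh-1, use of the downstream donor of a coding pair 18 nt apart was 32.1% ± 6.26 in R540K and 68.5% ± 5.17 in the control (n = 3 each), and an overlapping first exon event was 26.2% ± 3.84 against 59.1% ± 5.89 (n = 3 each). Inclusion of a group of unc-52 exons was 79.9% ± 0.48 in R540K and 92.8% ± 1.31 in the control (n = 3 each). Retention of an intron of chat-1, a CDC50-family chaperone gene, was 8.54% ± 1.55 against 18.7% ± 1.94 (n = 3 each). The crh-1 donor pair, at chromosome III, 11675567 to 11676387, fell by 36.4 points (SE 3.53; limma, adjusted p = 0.0139), and its first exon event fell by 32.9 points (SE 3.62; limma, adjusted p = 0.00526). The unc-52 event, in the coding region at chromosome II, 14656253 to 14658259, fell by 12.9 points (SE 1.08; limma, adjusted p = 0.00106) and was the 1 called event of 29 muscle genes, also when adjusted over the list alone. The other 9 lists had no limma call over 130 genes, with 23 of 390 events at an unadjusted p below 0.05 and 0 called adjusted over the list alone. F11A10.5 fell by 20.1 points at a donor pair and C24H10.3 fell by 20.4 points at an acceptor pair.

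Of 10291 donor and acceptor pairs, R540K changed 6, with 2 higher and 4 lower, where 570 had an unadjusted p below 0.05, and of 2207 annotated events it changed 6, with 1 higher and 5 lower. The 6 annotated calls lay in 4 genes. The 3 called first exon events among them were all lower and all in crh-1, where they overlap each other and the called donor pair. The calls in crh-1 need not be separate changes. Donor pairs gave 4 of the 12 calls, 3 lower and 1 higher (Fisher's exact test against other types, p = 1; exact binomial test of direction, p = 0.625). None of the 6 calls at donor and acceptor pairs stood without control replicate 2 or 3 or in a fit to the 6 libraries alone, and 3 and 2 were left without R540K replicates 1 and 2 and 3 without N18K replicate 3. The calls of C24H10.3 and Y43F8B.23 were also lost on logit PSI. Among annotated events, unc-52, H01G02.3 and the crh-1 first exon event kept their calls without any 1 of the 6 libraries, while chat-1 lost its call without control replicate 1 or 3 or R540K replicate 1 or 2. In a fit to the 6 libraries alone 1 annotated call was left, and at a minimum of 20 points 2.

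**Figure D4:**
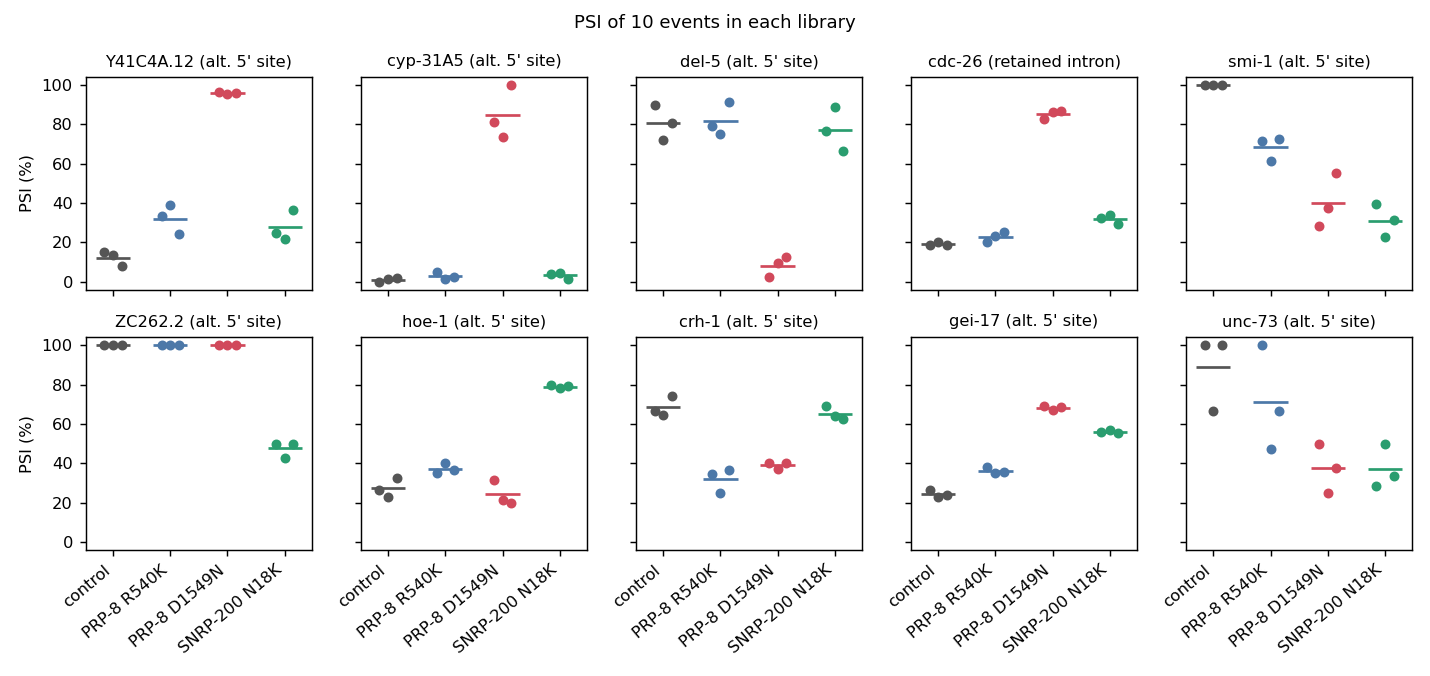
PSI in percent of 10 named events in each library, with 1 point per library and a line at each strain's mean. The Y41C4A.12, cyp-31A5, del-5 and cdc-26 events stand apart in D1549N, ZC262.2 and hoe-1 in N18K, crh-1 is low in both PRP-8 strains, gei-17 is above the control in all mutant strains, and the 3 control libraries of the 23 nt unc-73 pair run from 66.7% to 99.9%.

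Called in all 3 mutant strains were 4 events, in gei-17, F32D8.7, Y43F8B.23 and H01G02.3. The SUMO ligase gene gei-17 used the downstream donor of a pair 48 nt apart at 24.4% ± 1.92 in the control, 36.2% ± 1.45 in R540K, 68.3% ± 0.84 in D1549N and 56.1% ± 0.73 in N18K (n = 3 each; chromosome I, 9102823 to 9103106). At F32D8.7, use of the upstream acceptor was 42.7% ± 3.4 in the control and 65.5% ± 1.96, 59.7% ± 2.19 and 62.6% ± 3.85 in R540K, D1549N and N18K (n = 3 each; coding, chromosome V, 10899347 to 10899679). Y43F8B.23 used its unannotated downstream donor at 32.8% ± 7.52 in the control and at 0.1%, 7.07% ± 6.06 and 0.1% in the same order (n = 3 each), and H01G02.3 rose from 86.3% ± 2.09 to 99.9%, 98.8% ± 1.83 and 99.9% (n = 3 each). R540K and D1549N shared 5 called donor and acceptor pairs in the same direction and 0 in opposite directions. Of these, 2 were higher against 0.035 for independent lists and 3 lower against 0.11, the mean overlap in simulations of unchanged strains with shared controls was 0.04 (highest 1), and the overlap was 0 without control replicate 2 or 3. R540K and N18K shared 3 (simulated mean 0.05, highest 1), also 0 without control replicate 2 or 3. D1549N and N18K shared 50 in the same direction, 27 higher against 0.76 for independent lists and 23 lower against 1.1 (simulated mean 0.05, highest 1), and 4 in opposite directions. The simulated number leaves out the effects and the number for independent lists leaves out the shared controls, so the excess over either is not a measure of a shared effect. Without N18K replicate 3 the shared number was 93. Among annotated events D1549N and N18K shared 14, all higher and 11 of them retained introns including rsp-5 and T19D12.2, R540K and D1549N shared 4, and R540K and N18K shared 1 in the same direction and 1 in opposite directions, the chat-1 intron (18.7% in the control, 8.54% in R540K and 41.98% in N18K, n = 3 each). All comparisons used the same 3 control libraries. With 1 strain called against 2 of them and the other against the third alone, D1549N and N18K shared 12 to 25 calls in the same direction and 1 to 3 in opposite directions, R540K and D1549N 0 to 3 and 0 to 1, and R540K and N18K 0 to 2 and 0 to 1. Across events, which are not independent, the covariance of PSI differences was 31.7 squared points for D1549N with N18K against 11.9 in simulations of unchanged strains, 20.1 for R540K with D1549N against 11.8, and 20.4 for R540K with N18K against 11.8. The correlations were no higher than simulated, at r = 0.43, 0.34 and 0.44 in the same order against 0.5, 0.5 and 0.49. Shared controls alone give the simulated r, and effects found in 1 strain only lower r. These correlations therefore cannot count for or against a shared effect. With 3 control libraries no split into groups of at least 2 exists, so part of the excess overlap may come from the shared controls.

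Compared directly, the PRP-8 strains differed most at unnamed donor pairs and at cyp-31A5. Use of the downstream cyp-31A5 donor was 2.96% ± 1.8 in R540K and 84.8% ± 13.6 in D1549N (n = 3 each; limma, adjusted p = 2.9e-05). A pair 6 nt apart at chromosome II, 14400607 to 14400786, had a PSI of 99.9% in every R540K library and 0.1% in every D1549N library (limma, adjusted p = 0.00692). This pair varied widely within the control, at 0.1%, 60% and 75%, and stood at 66.67%, 62.5% and 40% in N18K, values that few reads can give. An acceptor pair at chromosome V, 18780978 to 18781698, had 0.1% in every R540K library against 78.9% ± 8.09 in D1549N (n = 3 each; limma, adjusted p = 0.00865). At the crh-1 donor pair, where both PRP-8 strains lay below the control, R540K minus D1549N was -7.02 points (limma, adjusted p = 0.353). Calls numbered 405 of 10291, with 251 higher in R540K and 154 lower, and 51 of 2207 annotated events, with 16 higher and 35 lower. All 30 called retained introns were lower in R540K than in D1549N (exact binomial test, p = 1.86e-09). In a fit to the 6 libraries alone the 405 calls became 237.

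R540K and N18K differed at fewer events. ZC262.2 used its downstream donor at 99.9% in every R540K library against 47.6% ± 4.12 in N18K (n = 3 each; limma, adjusted p = 3.12e-06). The limits given for this pair in N18K against the control apply here too. At dmsr-1, the values were 77.9% ± 3.65 and 25.5% ± 4.99 (n = 3 each; limma, adjusted p = 0.00848), a call lost on logit PSI, and at an unnamed pair at chromosome II, 3806699 to 3806913, they were 96.6% ± 5.72 and 26.2% ± 6.18 (n = 3 each; limma, adjusted p = 0.000623). At the crh-1 donor pair, R540K minus N18K was -33.1 points (limma, adjusted p = 0.00283). The alpha-sarcoglycan gene sgca-1 had 99.9% in every R540K library and 50.9% ± 12.3 in N18K (n = 3 each) at a donor pair 3 nt apart, a call lost without any R540K library or N18K replicate 1. Calls numbered 65 of 10291, with 34 higher in R540K and 31 lower, and 25 of 2207 annotated events, with 4 higher and 21 lower, and 15 of the 25 were retained introns, all lower in R540K (exact binomial test, p = 6.1e-05). The 65 calls became 130 without N18K replicate 3 and 21 in a fit to the 6 libraries alone.

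Between D1549N and N18K, the largest difference was at T16H12.3, where use of the downstream donor of a coding pair 6 nt apart was 95.1% ± 1.47 in D1549N, 8.34% ± 4.73 in N18K and 51.3% in the control as a mean of its 3 libraries (chromosome III, 10081677 to 10081925; limma, adjusted p = 4.49e-05 between the mutants). At cyp-31A5 the values were 84.8% ± 13.6 and 3.28% ± 1.52 (n = 3 each; limma, adjusted p = 3.4e-05). Donor pairs without a matched gene at chromosome III, 6121421 to 6121867 and 778093 to 778730, were higher in D1549N by 83.2 points each. The nuclear receptor gene nhr-1 went the other way in its 5' UTR, with 10.03% ± 9.95 against 90.7% ± 8.43 (n = 3 each), a call lost on logit PSI and without D1549N replicate 1 or 2 or N18K replicate 2 or 3. D1549N minus N18K was -26.1 points at the crh-1 donor pair (limma, adjusted p = 0.00237). Calls numbered 346 of 10291, with 151 higher in D1549N and 195 lower, and 44 of 2207 annotated events, with 25 higher and 19 lower. Retained introns were higher in D1549N in 19 of 23 calls, and in 19 of 22 genes (exact binomial test, p = 0.000855). The 346 calls became 175 in a fit to the 6 libraries alone.

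At unc-73 itself, the guanine nucleotide exchange factor gene that carries the mutated splice site, a coding donor pair 23 nt apart at chromosome I, 4021690 to 4022022, was measured. Use of the unannotated downstream donor was 88.8% ± 19.2 in the control, 71.3% ± 26.6 in R540K, 37.5% ± 12.5 in D1549N and 37.3% ± 11.3 in N18K (SD, n = 3 each). Single libraries held values such as 66.67%, 50% and 33.33%, so these means may rest on few reads. The differences from the control of -51.3 points in D1549N (SE 14.5; limma, adjusted p = 0.067) and -51.5 points in N18K (SE 14.5; limma, adjusted p = 0.184) were not called over all events. Adjusted over the list alone, the p-values were 0.0103 and 0.0202, and in R540K 0.689. On this list of strain-marking genes, 1 event adjusted over the list alone was called in N18K, 0 in R540K and 2 in D1549N, the second being the 45 nt pair. The mutations were selected for their effect on this allele, so that adjustment is not independent evidence, and prp-8 and snrp-200 had no tested event.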

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

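All tests of explanations in this part, the splits of the libraries among them, were chosen after the results were seen.

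The difference from the control itself differed between mutant strains, by limma's direct contrast, in 405 donor and acceptor events for R540K against D1549N, 65 for R540K against N18K and 346 for D1549N against N18K. Among annotated events the numbers were 51, 25 and 44. D1549N and N18K moved 4 donor pairs in opposite directions, each past the threshold in both. At zip-4, a bZIP transcription factor gene, the downstream donor was used at 42.0% in D1549N, 26.8% in the control and 11.4% in N18K, a difference between the mutants of 30.6 points (SE 2.32; limma, adjusted p = 6.81e-05; chromosome I, 3264413 to 3264598). T16H12.3 stood at 95.1%, 51.3% and 8.34% in the same order, a difference of 86.8 points. The gene pot-3, a homolog of the telomere-binding protein POT1, stood at 53.7%, 40.6% and 3.83%, a difference of 49.9 points (SE 3.04; limma, adjusted p = 1.91e-05; chromosome III, 13780400 to 13780589). A pair without a matched gene at chromosome IV, 4743364 to 4744255, which overlaps the called hoe-1 pair, stood at 14.2%, 46.1% and 72.1%, a difference of -57.9 points (SE 2.73; limma, adjusted p = 4.68e-06). R540K and N18K moved retention of the chat-1 intron in opposite directions, with R540K minus N18K at -33.4 points (SE 1.19; limma, adjusted p = 2.65e-06).

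Events with a value in all 3 libraries of a mutant strain and in no control library were not part of the tests. D1549N had 64 such donor and acceptor events, 40 of them donor pairs, against 30 with a value in all control libraries and no D1549N library, and 13 annotated events against 6, in genes such as dyf-13, glr-2, mgl-3 and rig-5. R540K had 17 donor and acceptor events against 15 in reverse and 2 annotated events against 4. N18K had 37 donor and acceptor events against 58 in reverse, and 5 annotated events against 4.

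Splitting the 6 libraries of each comparison in other ways gives 10 splits, too few for a share under 0.05, and in each comparison the real split was the 1 split with as many calls. For R540K, D1549N and N18K against the control, the real counts of donor and acceptor events were 6, 451 and 87, and the highest count of any other split was 1 each time. Between mutants they were 405, 65 and 346, with highest other counts of 1, 2 and 3. For annotated events the real counts were 6, 77 and 21 against the control and 51 and 44 for R540K and N18K against D1549N, and every other split gave 0. For R540K against N18K the real count was 25 and the highest other was 20, from the split that puts R540K replicates 1 and 2 with N18K replicate 3, which points to a structure of the samples beside the strain.

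The shift of D1549N at donors 3 and 4 nt apart is the first pattern weighed. Errors in aligning reads or building events that act on every library alike would by themselves give no difference between strains. The values below are therefore no test of such errors. At pairs called without 1 D1549N library, that library still lay at least 21.81 points outside the 6 libraries of the other mutants, which ranged over at most 5.67. The shift thus repeated across the D1549N libraries, which does not tell where it comes from. Over all tested pairs the D1549N libraries lay outside the other 9 by 1.49 points at 4 nt (range of those 0.83) and 3.22 at 3 nt (range 1.39), but not beyond that range without the called pairs (0.32 and -0.19), and an error limited to the D1549N libraries was not tested. Variants linked to 1 locus of the strain would cluster, and the most on any chromosome was 20.9% (14 of the 67 events, on chromosome V). Since each mutation was present in 1 strain, the PRP-8 change and any other difference of that strain remain open, and no test here separates them.

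Lower use of the upstream acceptor in D1549N, as at icd-2, is the second. Depth as the whole cause is argued against, though only by an indirect measure of it, the share of events at 0 or 1: the control libraries ranged over 0.66 points in mean acceptor use at pairs 6 nt apart while their share ran from 36.8% to 46.7%, and the mean share in D1549N differed from theirs by -0.06. A part for depth stays open, since the N18K libraries had shares of 49.2%, 43.3% and 38.6% with acceptor use of 38.2%, 37.0% and 43.5%, and within strains the 2 measures had r = -0.56 (permutation p = 0.191). Whether the strain alone sets this measure was not decided. The N18K libraries differed among themselves by 6.54 points where D1549N differed from the control by -4.69, but that range rests on N18K replicate 3. The ranges were smaller than the D1549N difference in D1549N itself (1.99 points), in R540K (3.84) and in the control. A factor that differs between libraries of 1 strain, of culture or technical, may contribute: the slope on acceptor use within R540K and N18K correlated with the D1549N difference at r = -0.697 across 64 mutually exclusive exon events, which are not independent. This was the strongest Pearson r of 8 event types, with -0.301 at acceptor pairs and -0.0194 at donor pairs. By Spearman rho last exons came first, at -0.628 against -0.62. What the D1549N strain adds was not separated.

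More retention of introns such as those of cdc-26, rsp-5 and rpl-12 in D1549N and N18K is the third. Unspliced RNA or DNA over the whole library would raise introns together, but the median difference in D1549N was 1.19 points (quartiles -1.64 and 7.82) and in N18K 1.71 (quartiles -1.72 and 6.75) over 295 introns between 5% and 95% in the control. Of these, 61 were higher and 14 lower by at least 10 points in D1549N, and 58 and 12 in N18K. Over all 722 tested introns, library means ran from 50.82% to 50.99% in D1549N and from 50.27% to 50.6% in N18K. They ran from 48.57% to 49.03% in the control and from 48.74% to 49.02% in R540K. The called introns are part of these means, so how many introns carry the difference was not separated. A smaller shift of many introns is not excluded. A factor between libraries, if taken as linear in acceptor use within strains, gives a rise of 2.88 points (SE 0.56) for the 35 introns, against 26.9 observed in D1549N, and 2.12 (SE 0.41) against 12.97 in N18K. These introns were chosen for a called rise of at least 10 points in D1549N, so the excess there was set by the choice. The N18K value rests on the same introns and control libraries and is not free of that choice. Such a factor is therefore not excluded. An effect of the mutations is a hypothesis that these values leave open, found and tested on the same libraries.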

How the results depend on the processing

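Omission of events at 0 or 1, the trend and robust settings, 3' splice site direction, the splicing regulator list and, for annotated events, all settings other than the larger minimum, logit PSI and leaving out libraries were tested only after the results were seen. Of 256 comparisons of a result with an alternative, 174 kept their side of the threshold or stayed within 1.5 times, 80 moved further, 1 became significant and 1 reversed. The cause was not tested except where the alternative's own construction gives it, as for a larger or no minimum difference or event types left out. A minimum of 20 points gave 242 calls for D1549N and 49 for N18K at donor and acceptor pairs, 238 for R540K against D1549N, 38 for R540K against N18K and 192 for D1549N against N18K, and 2, 33 and 10 annotated calls for R540K, D1549N and N18K. With no minimum these counts were 912, 140, 821, 101 and 759, and the annotated counts for D1549N and N18K 118 and 45. In a fit to the 6 libraries compared, R540K had 0 calls, N18K 17, and the comparisons between mutants 237, 21 and 175, with 1 annotated call for R540K and 11 for N18K. Under the rule on library pairs R540K had 23 calls, D1549N 267, R540K against D1549N 233, D1549N against N18K 194, and annotated D1549N events 46. Without events at 0 or 1 there were 11 for R540K, 195 for D1549N against N18K and 33 annotated for N18K. Without retained introns the annotated calls were 29 for D1549N and 4 for N18K. The annotated set in place of library introns gave 77 and 21 for D1549N and N18K, and 51, 25 and 44 between mutants, being other event types.

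With each library left out in turn, calls ran from 0 (without control replicate 2 or 3) to 9 for R540K, from 57 (without control replicate 1) to 175 (without N18K replicate 3) for N18K and from 48 to 130 (without N18K replicate 3) for R540K against N18K, and stayed within 1.5 times for D1549N (330 to 511). Leaving out N18K replicate 3 left 3 calls for R540K. Annotated calls ran from 43 (without control replicate 2) to 96 for D1549N and from 14 to 70 (without N18K replicate 3) for N18K. The odds ratio of donor pairs ran from 0 to 1.32 for R540K, with 1.32 at a minimum of 20 points and 1.1 on logit PSI, and for N18K from 0.832, reversed without replicate 3, to 6.05. The share of N18K genes or loci moving away from the downstream donor was 47.7% at a minimum of 20 points and 48.4% on logit PSI, and its share for the upstream acceptor ran from 0% to 96.7% (without N18K replicate 3, exact binomial p = 5.24e-23). The shared calls of R540K and D1549N ran from 0 (without control replicate 2 or 3) to 8, with 2 at 20 points. Those of R540K and N18K ran from 0 (again without control replicate 2 or 3) to 6, with 1 at 20 points and 1 in the annotated set. D1549N and N18K shared from 35 to 93 (without N18K replicate 3), with 25 at 20 points and 14 in the annotated set. The odds ratio of the splicing regulator list in D1549N ran from 4.5 to 6.67 without single libraries, and was 5.16 on logit PSI and 9.88 at a minimum of 20 points.

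Among named events, 534 of 679 comparisons with logit PSI or a library left out kept their side of the threshold, 145 lost the call and 0 reversed. Of 89 named calls, 53 held on logit PSI and without any single library of their comparison. Read minimums and count-based tests with edgeR or DESeq2 were not run because the files hold no counts, and the share and direction of donor events could not be taken from the annotated set, which has none. No paired analysis was possible because replicate numbers follow accession order only. Unknown depth limits all values, and a PSI at 0 or 1 can rest on few reads.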

Other observations

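The tests in this part were all chosen after the results were seen, and genes named for the first time here were picked after their values were known.

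In D1549N and N18K, called changes kept the reading frame more often than other pairs did. Among coding donor pairs in D1549N, 111 of 222 called pairs lay a multiple of 3 nt apart (50%), against 29.4% of 3193 not called (Fisher's exact test, adjusted p = 1.89e-09 over 6 tests). Among coding acceptor pairs in D1549N, 98 of 108 did (90.7%), icd-2 and B0001.7 among them, against 47.6% (adjusted p = 2.85e-20). In N18K the shares were 32 of 53 donor pairs (60.4%) against 30.2% (adjusted p = 1.5e-05) and 7 of 7 acceptor pairs against 48.5% (adjusted p = 0.00952), and in R540K, with few calls, 2 of 3 donor pairs against 30.7% (adjusted p = 0.27) and 1 of 2 acceptor pairs against 48.6% (adjusted p = 1). Pairs 6 nt apart, the distance with the most acceptor calls, keep the frame, so distance and frame are not separate here.

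An intron of tos-1, whose transcript is used as a read-out of splicing in worms, was retained at 19.4% ± 0.79 in the control, 16.2% ± 1.17 in R540K, 41.6% ± 2.54 in D1549N and 34.9% ± 5.15 in N18K (SD, n = 3 each; chromosome V, 9343652 to 9344105). Retention rose by 22.2 points in D1549N (limma, adjusted p = 0.000929) and by 15.6 points in N18K (limma, adjusted p = 0.0106). Over the 35 introns that rose in D1549N, N18K had a mean of 32.03% ± 1.97 and R540K of 21.8% ± 1.95, with 19.1% ± 0.6 in the control and 46.0% ± 0.36 in D1549N (SD, n = 3 each).

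On average, donor pairs called in N18K lay between the control and N18K in the other mutants, though single pairs such as those of ZC262.2 and hoe-1 did not in D1549N. The 41 pairs that rose in N18K had means of 35.7% in the control, 43.8% in R540K, 56.1% in D1549N and 64.3% in N18K, and the 38 that fell had 71.2%, 68.4%, 56.2% and 44.3% (n = 3 libraries each). To keep the controls apart, events were called without 1 control library and the other strain was set against that library alone. Without a change, equal signs need not make up 50% of events. Near the lowest or highest PSI, a mean of 3 libraries leaves the limit more often than 1 library does, and equal values were left out. The share that unchanged strains would give can therefore exceed 50% and was not measured, so the shares below do not show a shared change. For calls of N18K, equal signs in D1549N made up 78.3% to 82.2% over the 3 control libraries (47 of 60 to 60 of 73 events that differed), and 62.7% to 69.6% in R540K. For calls of D1549N they made up 72.8% to 73.9% in N18K and 54% to 59.8% in R540K. Events of 1 gene are not independent, and these shares were not tested.

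Within strains, libraries with lower use of the upstream acceptor at pairs 6 nt apart had more retention of the 35 introns that rose in D1549N (Pearson r = -0.89 over deviations of 12 libraries from their strain means, permutation p = 0.0116, adjusted p = 0.0463 over 4 relations; Spearman rho = -0.825, permutation p = 0.0108). With the 2 libraries farthest from the median left out of the correlation but kept in the strain means, r was -0.857. That value is therefore not free of those libraries. The same acceptor measure had r = -0.56 with the share of events at 0 or 1 (permutation p = 0.191), 0.401 with the donor pairs 4 nt apart (permutation p = 0.383) and 0.108 with those 3 nt apart (permutation p = 0.775). A factor that differs between libraries of 1 strain, technical or such as the mix of stages, is a candidate explanation, and it gave r = -0.697 across mutually exclusive exon events for the D1549N difference. For other event types that r was -0.0194 at donor pairs, -0.301 at acceptor pairs, -0.504 at skipped exons, -0.414 at runs of skipped exons, -0.619 at last exons, -0.28 at first exons and -0.29 at retained introns. The mix of stages itself was not analysed here, because the files hold no expression values.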
